A study of Mus musculus with 12 samples.

How the data were processed

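Total RNA from mouse spleen was hybridised, with a biotin label, to 12 single-channel Affymetrix arrays. The labels place the arrays in 6 groups of 2, made of 2 sexes at 3 ages: 3-4 weeks, 6-9 weeks and 24-28 weeks, which the design text calls before, at and after puberty. The strain of the mice is not given in the sources used here. The 2 arrays of a group carry the letters a and b. Nothing in the labels says that they came from separate animals, so p-values measure only the spread between these arrays, which may be technical.

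The deposited values are linear intensity values, the MAS5 signal of each probe set, which the authors computed with MAS5 per the submitters' processing notes. The MAS5 version, the scanner and the scaling target are not given in the sources used here. The deposited columns all had nearly the same mean after trimming 2% of the values at each end, between 800.5 and 800.7, so the arrays had been scaled before deposit. Detection calls were not used here, so no statement is made on which genes lay above background. The table holds 12488 probe sets. Of these, 66 were control probe sets, which were left out of all tests. Of the other 12422, 10833 had 1 gene symbol in the platform annotation, 396 had several and 1193 had none in the table used. Only probe sets with 1 symbol were named. Symbols were checked through the Entrez identifier against a mouse gene table of assembly GRCm38.p6, used for names only: 10817 were already current, 0 were updated and 16 were kept without a match. No genome sequence was used. Probe sets whose identifiers end in _s_at, _f_at, _r_at or _i_at can match related transcripts or do not meet all probe design rules. Of the genes named, Eif2s3y, Sry, Ighv1-54, Igkv4-91, Igkv6-14, Igkv8-19, Igkv8-30, Igkv9-120, Igkv14-111, Ins2, Klk1, Ctrl, Ctrb1, Ppy, Reg3b, Anxa1, Gm9706, Hemgn, Kcnab2, Pou2f2, Rhag, Fcgr1 and Uqcrc2 are measured by such probe sets, and their identity is therefore uncertain.

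Each array was rescaled to a trimmed mean of 500, 32 was added and log2 was taken. All log2 differences are on this scale, which understates the change of dim genes. Signals given for a group are means of the scaled signal with the SD over 2 arrays. Probe sets were tested if their scaled signal reached 100 on at least 2 of the 12 arrays. This kept 8926 probe sets, which represent 6539 gene symbols, and left out 3496. The number of arrays limits the precision of every estimate.

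A linear model with a mean for each of the 6 groups was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3. The shared fit has 6 residual degrees of freedom and 5.43 prior degrees of freedom. The comparisons were male minus female averaged over the ages and at each age, the 3 differences between ages averaged over the sexes, and a moderated F test of whether the sex difference changed with age. P-values were adjusted by the method of Benjamini and Hochberg over the 8926 probe sets, with a threshold of 0.05. The rule for named genes took, for the averaged comparisons, the 10 largest increases and 10 largest decreases among genes past the threshold whose arrays on one side all lay beyond those on the other. For each sex difference within an age and for the interaction it took the 10 smallest p-values. It also took up to 4 members with the smallest p of each list described, Xist and the Y-linked genes. A gene with several probe sets was represented by the brightest.

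The model, the filter, the offset, the naming rule, most of the alternatives and 27 gene lists were fixed before the data were examined. The lists cover Y-linked genes, X inactivation and escape, B cells, immunoglobulins, plasma cells, T cells, NK and cytotoxic cells, neutrophils and granule proteins, red pulp macrophages and monocytes, dendritic cells, MHC class II, erythroid cells, platelets and megakaryocytes, cell cycle, interferon-stimulated genes, sex steroid and glucocorticoid genes, cytokines and chemokines, complement, stroma and matrix, endothelium, pancreas, adipose tissue, skeletal muscle, liver, immediate early and heat shock genes, ribosomal proteins and oxidative phosphorylation. Each list was tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes and 1 probe set per gene, and adjusted over the lists of a comparison. Camera compares a list with all other genes, so a list is called higher or lower relative to them. Members were counted at the threshold over all probe sets and also adjusted over the list alone. The same tests were repeated with a correlation estimated from the residuals.

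The procedure was tested on simulated data for 8926 probe sets. For the averaged sex difference, simulated changes of 0.5, 1 and 2 log2 units were recovered in 55.2%, 89.6% and 100% of changed probe sets. For the sex difference at 3-4 weeks the shares were 14.9%, 56.7% and 90.9%, and at 24-28 weeks 7.5%, 59.7% and 92.4%. For 6-9 against 3-4 weeks they were 37.3%, 79.1% and 98.5%, and for 24-28 against 3-4 weeks 46.3%, 85.1% and 93.9%. For the interaction they were 1.5%, 31.3% and 77.3%. In these comparisons between 2 and 14 of 8726 unchanged probe sets were called. The list test recovered 1 shifted list of 25 genes for the comparison of 6-9 with 3-4 weeks, and called 0 of 20 unshifted lists. The simulated genes varied independently, so this does not show how often the list test calls unshifted lists of correlated genes.

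The alternatives were the values as deposited, quantile normalization, offsets of 1 and 100, no filter and a filter at 200, eBayes without the trend and with robust estimation, the letter a or b as a block, array weights, fits to only the groups compared, 1 probe set per gene, and leaving out each array in turn. Fits without the male 24-28 week arrays and without the male 6-9 week arrays were added after seeing the data, because these arrays had the highest and lowest 3'/5' signal ratios of the beta-actin control. In those fits a comparison that needed the missing group used females only, or the remaining ages. Figures were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.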

Results

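Gene expression was measured in the spleens of male and female mice at 3-4, 6-9 and 24-28 weeks of age, with 2 arrays in each of the 6 groups of sex and age. The deposited MAS5 signals had a median between 245 and 337 on the 12 arrays, and between 59.4% and 65.0% of the probe sets reached a scaled signal of 100. The 2 arrays of a group correlated across probe sets at r = 0.970 to 0.974, and arrays of different groups at 0.917 to 0.969. These correlations are across genes, which are not independent replicates. The first 2 principal components held 36.6% and 15.1% of the variance. The ratio of 3' to 5' signal of the beta-actin control, a sign of RNA quality, differed between groups. It was 2.50 ± 0.159 (SD, n = 2) in males at 24-28 weeks and 0.355 ± 0.0304 in males at 6-9 weeks. In females it was 1.20 ± 0.241 at 3-4 weeks, 0.656 ± 0.116 at 6-9 weeks and 1.30 ± 0.0926 at 24-28 weeks, and in males at 3-4 weeks it was 1.11 ± 0.119. The Gapdh control ratio was lowest in males at 6-9 weeks, at 1.22 ± 0.226, and highest in females at 3-4 weeks, at 2.57 ± 0.491. The scaled beta-actin 3' signal was 6816 and 4045 in males at 6-9 weeks and 10399 or more on the other arrays. The 5' signal was 6871 and 7483 in males at 24-28 weeks and 12130 or more on the others. It is therefore uncertain whether the ratio measured RNA quality alike in all groups. The brightest deposited signal was 28490 on male replicate b at 6-9 weeks and 44639 or more on the others.

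**Figure D1:**
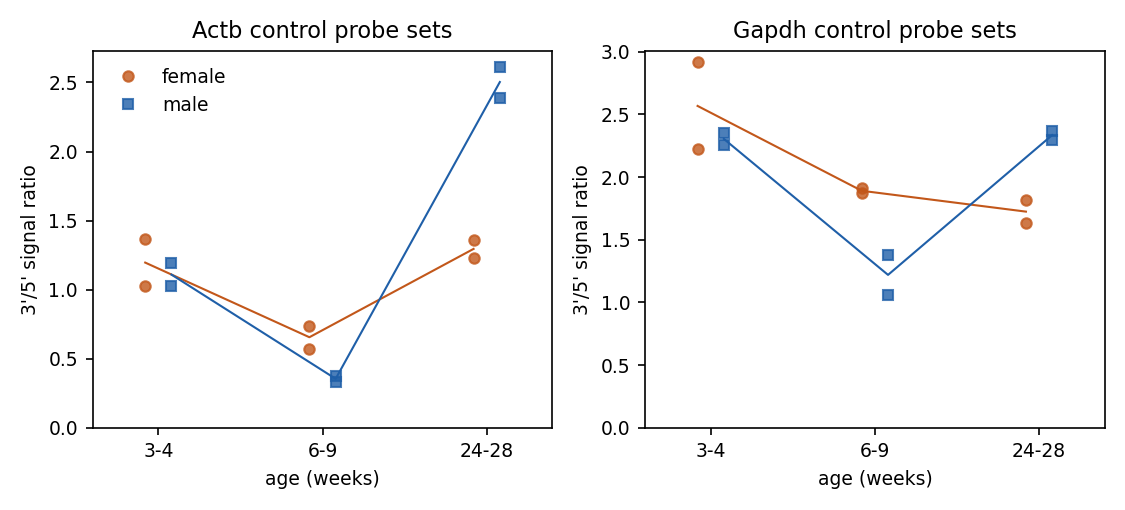
The ratio of 3' to 5' signal of the Actb and Gapdh control probe sets (vertical axes, no unit) is plotted against age in weeks for each array (orange circles, females; blue squares, males), and lines join the group means. The Actb ratio of the male 24-28 week arrays averaged 2.50, and the other 10 arrays lay between 0.333 and 1.37.

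The sex labels were checked first. Xist, the X-linked RNA of X inactivation, gave a scaled signal of 211 to 386 on the 6 female arrays and of 7.49 to 88.2 on the 6 male arrays. Eif2s3y, a Y-linked translation factor gene (an _f_at probe set), gave 24.5 to 57.6 in females and 658 to 987 in males. The Y-linked gene Uty was also higher in males, by 2.03 (SE 0.22, adjusted p = 0.000111). Uba1y (log2 difference −0.59, adjusted p = 0.119) and Sry (0.22, adjusted p = 0.522) did not pass, and Kdm5d was too dim to be tested. Of the 5 tested genes of the X inactivation and escape list, 4 were lower in males and 0 were higher, and adjusted over the list alone all 5 were lower (median −0.77, adjusted p = 3.93e-06). The list includes Kdm6a (−1.06) and Eif2s3x (−0.77). The Y-linked list was higher in males (2 of 4 members, median 1.12, adjusted p = 0.00278, and adjusted p = 0.0512 with an estimated correlation). Adjusted over the list alone, 2 of its members were higher and 1, Uba1y, was lower. Uba1y gave 78.7 to 136 on the female arrays and 23 to 94.4 on the male arrays. Females carry no Y chromosome, so it is uncertain whether its probe set measured that gene.

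**Figure D2:**
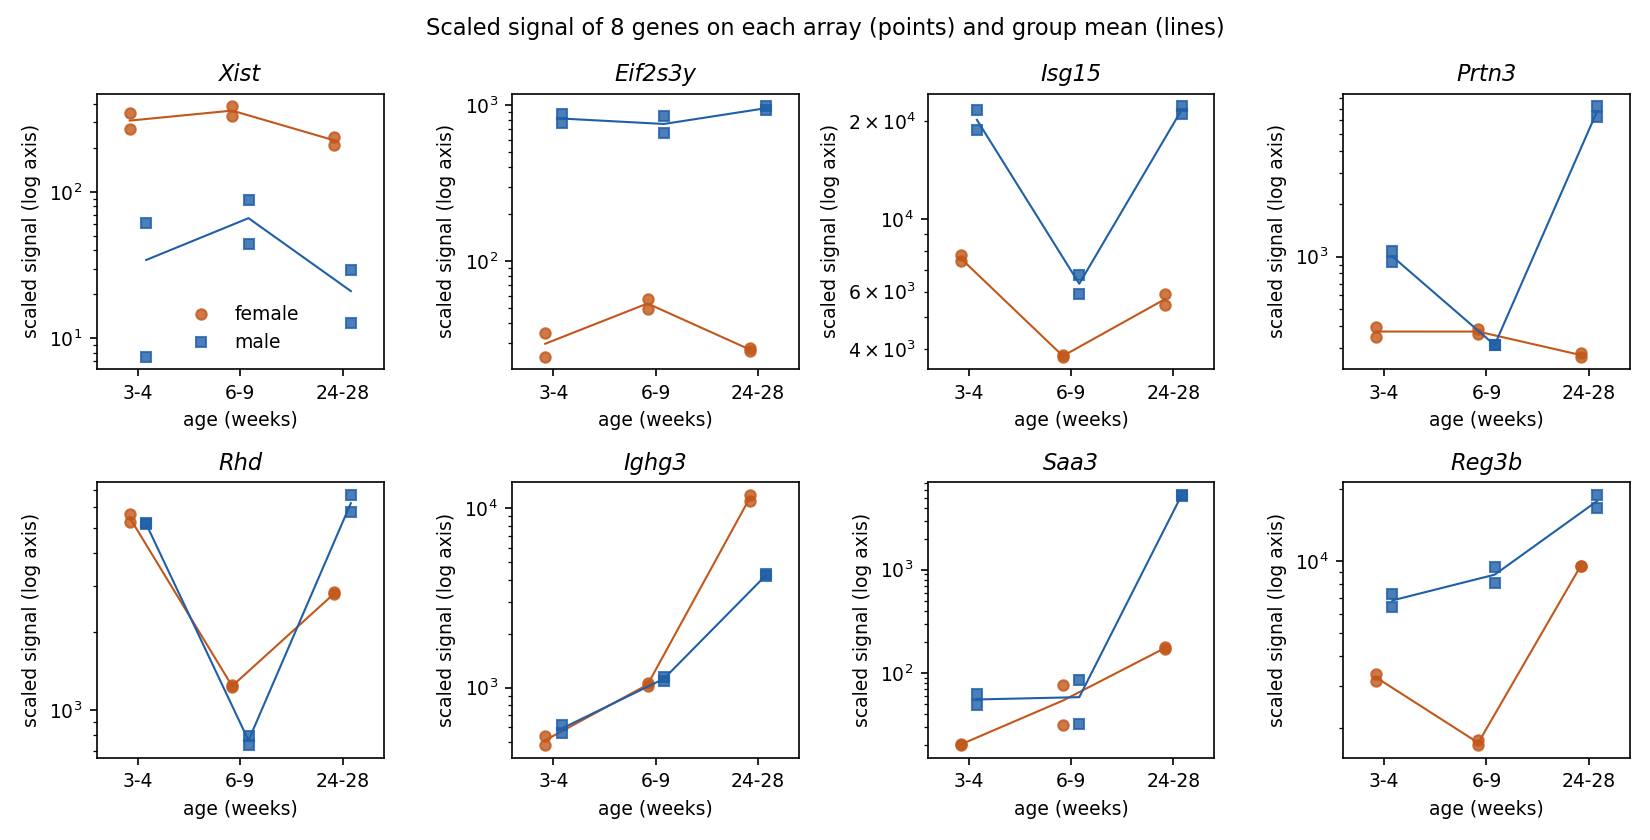
Scaled signal (log axis) of Xist, Eif2s3y, Isg15, Prtn3, Rhd, Ighg3, Saa3 and Reg3b is plotted against age in weeks for each array (orange circles, females; blue squares, males), and lines join the group means. Prtn3 reached 6736 in males at 24-28 weeks against 274 in females, and Rhd was lowest at 6-9 weeks in both sexes.

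The first comparison asked how male and female spleens differed when the ages were averaged. Genes of neutrophil granules and genes induced by interferon were higher in males, and genes of B cells, T cells and MHC class II antigen presentation were lower. The T cell and MHC class II lists were not called by camera without the male 24-28 week arrays (medians −0.10 and 0.03, adjusted p = 0.307 and 0.710). Of 22 B cell genes 3 were then lower. Of 19 neutrophil and granule genes, 16 were higher, 0 were lower and 3 were not called, and the mean of the list was higher on all 6 male arrays than on any female array. Prtn3 (log2 difference 1.86) and Elane (1.55), which encode granule serine proteases, Ltf (1.21), which encodes the iron-binding lactoferrin, and Ngp (1.41) had the smallest p-values. In that order they differed by 4.46, 3.77, 2.99 and 3.88 at 24-28 weeks. At 6-9 weeks they differed by −0.23, −0.04, −0.65 and −0.62, and the list was not called at that age. Of 28 interferon-stimulated genes, 19 were higher, 0 were lower and 9 were not called. They included Isg15 (1.35), a ubiquitin-like modifier, Usp18 (1.11), which removes it, Rsad2 (1.15) and Ifit1 (1.51).

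Among single genes in the averaged comparison, Slfn4 was higher in males by 2.74 (SE 0.11, adjusted p = 2.37e-08), with all 6 male arrays above all 6 female arrays, as the naming rule required. Its signal was 329 ± 102, 712 ± 12.1 and 533 ± 133 (SD, n = 2) in females and 2151 ± 50.7, 4074 ± 266 and 4864 ± 410 in males at the rising ages. The other genes named with such a separation and higher in males, besides Eif2s3y and Uty, were Wfdc21 (2.48), Ifitm6 (1.86), the haptoglobin gene Hp (1.76), the lipocalin gene Lcn2 (1.75), Chil1 (1.56), Ifit1 and the neutrophil surface marker gene Ly6g (1.43). Those lower in males were Xist, the B cell transcription factor gene Pou2f2 (−1.33), Kdm6a, Cpne6 (−0.87), Eif2s3x, Haus4 (−0.63), Ap1s1 (−0.60), Pik3c3 (−0.59), Fastkd5 (−0.56) and Slc25a15 (−0.39). In all, 791 of 8926 probe sets were called by limma, 336 higher and 455 lower in males. Without the male 24-28 week arrays 892 probe sets were called, of which 404 were among the 791, and without the male 6-9 week arrays 951 were called. Without the male 24-28 week arrays Haus4 (−0.70, adjusted p = 0.055), Pik3c3 (−0.34, 0.0768), Fastkd5 (−0.47, 0.147) and Slc25a15 (−0.30, 0.127) were not called, so that Haus4 had a larger difference with fewer arrays, and Fastkd5 was also not called without the male 6-9 week arrays (0.215). Leaving out any 1 of the 12 arrays ended the call of Fastkd5 (adjusted p = 0.0508 to 0.113), 9 arrays did so for Pik3c3 (0.0575 to 0.0867), 7 for Haus4 (0.0516 to 0.0894), and female replicate a at 3-4 weeks (0.0502) and male replicate b at 24-28 weeks (0.051) for Slc25a15. Without the filter on dim probe sets Haus4 (adjusted p = 0.0512) and Fastkd5 (0.0572) were not called, nor was Pik3c3 without the intensity trend in eBayes (0.0631).

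Camera called 13 of the 27 lists in the averaged comparison, 7 higher and 6 lower in males, and 7 of the 13 held with an estimated correlation. The neutrophil list had a median of 1.41 (adjusted p = 1.68e-27) and the interferon list one of 0.63 (adjusted p = 2.86e-25). Adjusted over the list alone, 16 neutrophil genes were higher, and 22 interferon genes were higher and 1 was lower. Of 22 B cell genes 11 were lower and 0 higher (median −0.38, adjusted p = 3.66e-09), among them the antigen receptor gene Cd79a (−0.68) and the kinase gene Blk (−0.64), and adjusted over the list alone 14 were lower. Of 22 T cell genes 12 were lower and 0 higher (median −0.48, adjusted p = 4.69e-09), among them the receptor genes Cd3e (−0.90) and Cd3d (−0.57), and adjusted over the list alone 15 were lower. Of 10 MHC class II genes 6 were lower and 0 higher (median −0.44, adjusted p = 2.51e-05), among them Cd74 (−0.73), and adjusted over the list alone 8 were lower. Macrophage and monocyte genes were higher (6 of 24 higher and 1 lower, the same adjusted over the list alone, median 0.08, adjusted p = 0.00207), among them the monocyte receptor gene Ccr2 (0.92).

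The lymphocyte lists moved with the male 24-28 week arrays, whose beta-actin ratio was 2.50. Without those arrays the T cell median was −0.10 (adjusted p = 0.307), the MHC class II median was 0.03 (adjusted p = 0.710) and the B cell median was −0.13 (adjusted p = 0.0189, with 3 of 22 lower). The interferon list then had a median of 0.77 (adjusted p = 1.27e-27, 24 of 27 higher) and the neutrophil list one of 0.56 (adjusted p = 2.43e-10, 10 of 19 higher). The pancreas list, which marks a neighbouring organ, was higher in males (9 of 20 higher, 10 adjusted over the list alone, 0 lower, median 0.30, adjusted p = 3.09e-07), with adjusted p = 0.119 with an estimated correlation. Its median was −0.11 (adjusted p = 0.0367, with 8 of 20 lower and 1 higher) without the male 6-9 week arrays and 0.94 (adjusted p = 1.45e-17, with 16 higher) without the male 24-28 week arrays. The macrophage median was 0.24 (adjusted p = 6.57e-05, with 5 of 24 higher) without the male 24-28 week arrays and 0.005 (adjusted p = 0.0367) without the male 6-9 week arrays.

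Further list calls in the averaged comparison were lost with an estimated correlation. Erythroid genes were higher (7 of 27 higher and 2 lower, 7 and 4 adjusted over the list alone, median 0.07, adjusted p = 0.0111, and adjusted p = 0.171 with an estimated correlation). That call was lost under quantile normalization (adjusted p = 0.121), and without the male 24-28 week arrays the median was −0.23 (adjusted p = 0.00298). NK and cytotoxic genes were lower (3 of 15 lower and 1 higher, 5 and 1 adjusted over the list alone, median −0.33, adjusted p = 0.0244, and adjusted p = 0.0994 with an estimated correlation). Plasma cell genes were lower (1 of 13 lower, Irf4 at −0.64, also adjusted over the list alone, median −0.15, adjusted p = 0.0359, and adjusted p = 0.171 with an estimated correlation), a call lost under quantile normalization (adjusted p = 0.0516). Without the male 24-28 week arrays the NK and plasma cell medians were −0.03 (adjusted p = 0.325) and 0.008 (adjusted p = 0.664). Liver genes were higher (1 of 7, which was Hp, 1 higher and 1 lower adjusted over the list alone, median 0.15, adjusted p = 0.0359, and adjusted p = 0.182 with an estimated correlation), and were not called without the filter on dim probe sets (adjusted p = 0.155). Leaving out male replicate a at 6-9 weeks ended the NK call (adjusted p = 0.0626), 6 single arrays ended the plasma cell call (0.0541 to 0.0966) and 7 the liver call (0.0601 to 0.0859).

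**Figure D3:**
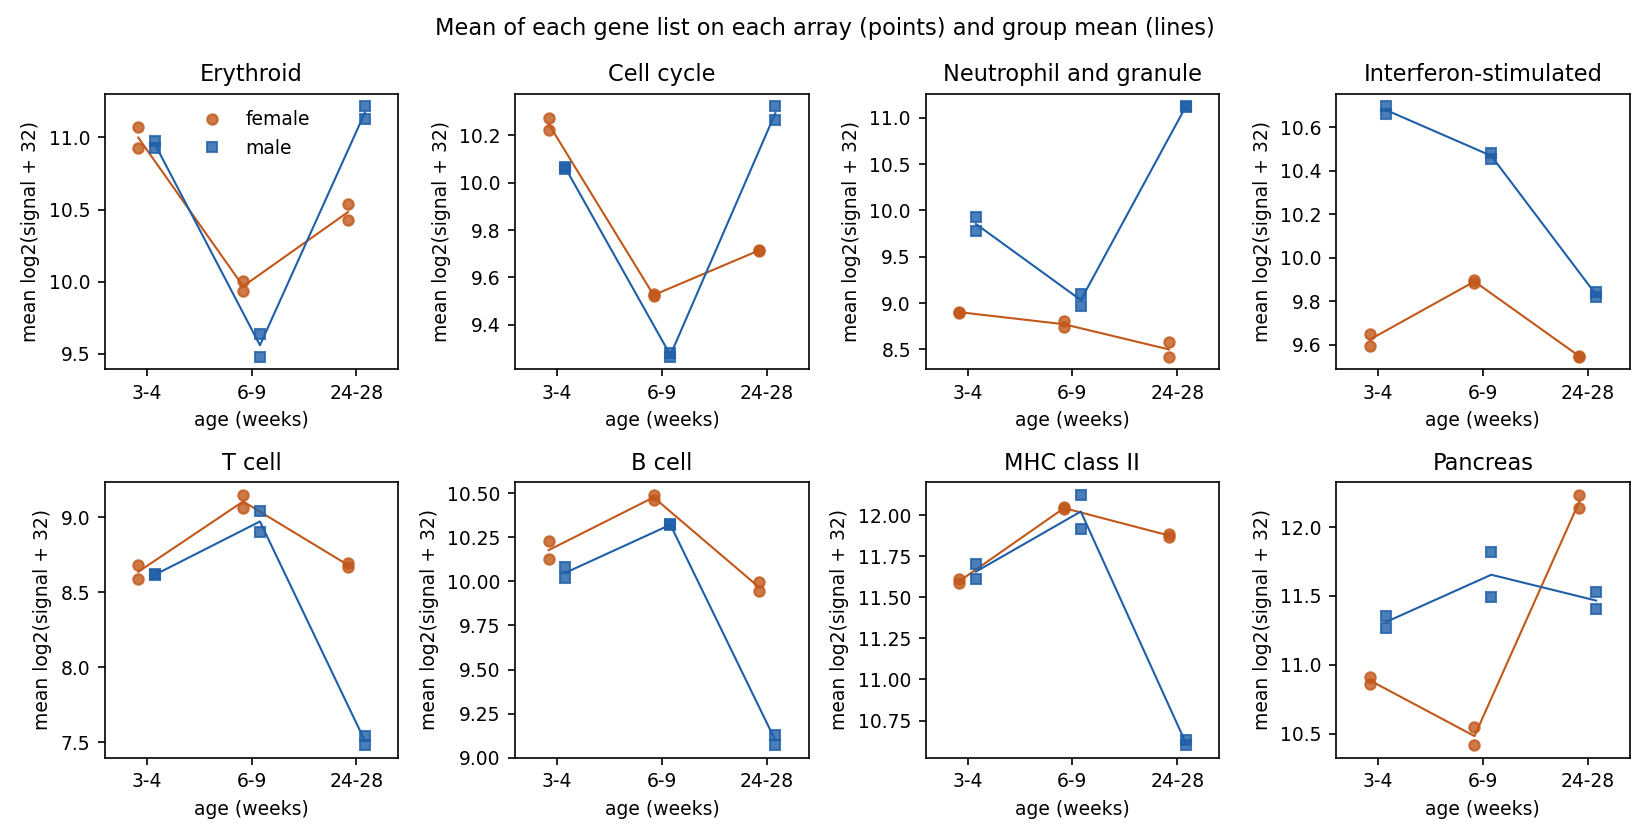
The mean log2(scaled signal + 32) of the genes of 8 lists is plotted against age in weeks for each array (orange circles, females; blue squares, males), and lines join the group means. Erythroid and cell cycle genes were lowest at 6-9 weeks in both sexes (median changes from 3-4 weeks −1.47 and −0.70), and neutrophil genes at 24-28 weeks were higher in males (median 2.99).

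At 3-4 weeks, before puberty, the interferon-stimulated genes stood above the rest of the genes in males. Of 28 members 22 were higher, 0 were lower and 6 were not called (median 0.97, adjusted p = 5.58e-39), and adjusted over the list alone 26 were higher. Isg15 gave 20151 ± 2031 in males against 7598 ± 221 in females (SD, n = 2), a log2 difference of 1.40 (SE 0.11, adjusted p = 3e-05). Ifit2 (2.23), Ifit1 (2.01), Iigp1 (1.79), Usp18 (1.72) and Ifit3 (1.61) were also among the 10 genes with the smallest p-values, with Eif2s3y (3.79), Slfn4 (2.62), Gm9706 (1.70) and Ltf (1.30). In all 10 both male arrays lay on one side of both female arrays. Of 19 neutrophil and granule genes 12 were higher and 0 lower (median 1.01, adjusted p = 2.01e-17), among them Prtn3 (1.35) and the cathelicidin gene Camp (1.23), and adjusted over the list alone 15 were higher.

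Also at 3-4 weeks, 8 of 53 cell cycle genes were lower in males and 0 higher (median −0.20, adjusted p = 9.13e-06), among them the replication genes Rrm1 (−0.92) and Fen1 (−0.65), and 12 were lower adjusted over the list alone. Macrophage and monocyte genes were higher (2 of 24, Fcgr1 at 1.08 and C1qb at 0.49, and 9 adjusted over the list alone, median 0.31, adjusted p = 6.2e-05). Oxidative phosphorylation genes were lower (3 of 63, and 8 adjusted over the list alone, median −0.13, adjusted p = 0.000863). Pancreas genes were higher (8 of 20 higher, 14 adjusted over the list alone, 0 lower, median 0.52, adjusted p = 3.95e-09, and adjusted p = 0.0779 with an estimated correlation). The dendritic cell (adjusted p = 0.00501), cytokine (0.0277), complement (0.0492) and stroma (0.0492) lists were called higher with medians of 0.18, 0.30, 0.09 and 0.16. With an estimated correlation these gave adjusted p = 0.0545, 0.0779, 0.117 and 0.0893. Of their members 1 of 12 dendritic cell genes, 0 of 25 cytokine genes, 1 of 12 complement genes and 0 of 35 stroma genes were higher, and adjusted over the list alone 1, 3, 3 and 0.

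Limma called 274 probe sets at 3-4 weeks, 165 higher and 109 lower in males. The count depended on single arrays: it was 106 without male replicate a, 113 without female replicate b, 119 without female replicate a and 144 without male replicate b of this age. It was 118 without the intensity trend in eBayes and 131 when only these groups were fitted. Camera called 12 of 27 lists, 9 higher and 3 lower, and 7 held with an estimated correlation. Complement genes were not called under quantile normalization (adjusted p = 0.063), and neither complement nor stroma genes with an offset of 1 (both 0.0508). Without the filter on dim probe sets the complement (adjusted p = 0.0728), stroma (0.0551) and cytokine (0.0605) lists were not called. Single arrays left out ended the complement call in 10 cases (adjusted p = 0.0543 to 0.170) and the stroma call in 4 (0.0564 to 0.227), and leaving out male replicate b of this age ended the cytokine call (0.250).

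At 6-9 weeks, at puberty, pancreatic genes were higher in males together with interferon-stimulated genes, and genes of the cell cycle and of oxidative phosphorylation were lower. Reg3b (an _s_at probe set), a secreted lectin gene, gave 8774 ± 965 in males against 1737 ± 56.9 in females (SD, n = 2), a log2 difference of 2.31 (SE 0.11, adjusted p = 5.86e-07). Reg3a (2.41), Reg2 (2.15), the kallikrein gene Klk1 (2.03), the zymogen granule gene Sycn (1.90) and the protease gene Ctrl (1.66) were among the 10 smallest p-values as well. The others were Eif2s3y (3.19), Lilr4b (1.61), the immunoglobulin A gene Igha (1.30) and Igkv14-111 (1.48). In all 10 both male arrays lay on one side of both female arrays. Of 20 pancreas genes 15 were higher, 1 was lower and 4 were not called (median 1.28, adjusted p = 2.19e-20), and adjusted over the list alone 18 were higher and 1 was lower. Whether the amount of pancreatic tissue in the samples differed between the sexes was not tested, at this age or in the other sex comparisons, and stays open. Of 28 interferon-stimulated genes 16 were higher and 0 lower (median 0.52, adjusted p = 2.52e-15), among them Ifit2 (1.45) and Gbp2 (1.03), and adjusted over the list alone 20 were higher.

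At this age 14 of 53 cell cycle genes were lower in males and 0 higher (median −0.24, adjusted p = 6.79e-07), among them Birc5 (−0.89) and Mcm5 (−0.86), and adjusted over the list alone 18 were lower. Of 63 oxidative phosphorylation genes 22 were lower and 3 higher (median −0.28, adjusted p = 8.14e-07), among them Uqcrc2 (−1.01), and adjusted over the list alone 30 were lower and 3 higher. Of 27 erythroid genes 12 were lower and 3 higher, the same adjusted over the list alone (median −0.50, adjusted p = 0.000259, and adjusted p = 0.0902 with an estimated correlation), among them the erythroid transcription factor genes Tal1 (−1.48) and Gata1 (−1.21). The beta-actin ratio was 0.355 in these males and 0.656 in these females. Neutrophil genes were not called (adjusted p = 0.551) and went both ways, with a median of −0.04 against a mean of 0.26. Of 19, 4 were higher, such as Mmp8 (2.29) and Il1b (1.63), and 3 were lower, such as Camp (−0.70) and Ltf (−0.65), and adjusted over the list alone 6 were higher and 4 lower.

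Further list calls at 6-9 weeks were lost with an estimated correlation. Macrophage genes were higher (3 of 24 higher and 1 lower, 7 and 2 adjusted over the list alone, median 0.26, adjusted p = 0.00312, and adjusted p = 0.0648 with an estimated correlation). Ribosomal protein genes were lower (5 of 28, and 10 adjusted over the list alone, median −0.48, adjusted p = 0.000471, and adjusted p = 0.319 with an estimated correlation), and were not called under quantile normalization (adjusted p = 0.254). B cell genes were lower (2 of 22, and 3 adjusted over the list alone, median −0.12, adjusted p = 0.0397, and adjusted p = 0.0943 with an estimated correlation), also not called under quantile normalization (adjusted p = 0.216). The immunoglobulin (median 0.43, adjusted p = 0.0187), dendritic cell (0.25, 0.0179) and cytokine (0.31, 0.0306) lists were higher, with adjusted p = 0.0943, 0.0902 and 0.0902 with an estimated correlation. They had 2 of 7, 2 of 12 and 2 of 25 members higher and 0, 0 and 1 lower, and adjusted over the list alone 2, 6 and 3 were higher and 0, 1 and 1 lower. Leaving out male replicate a of this age ended the B cell (adjusted p = 0.0934), immunoglobulin (0.0834), dendritic cell (0.0834) and cytokine (0.133) calls, and male replicate b the ribosomal call (0.128). Female replicate a ended the B cell (adjusted p = 0.124) and dendritic cell (0.0702) calls, and female replicate b the cytokine call (0.0665).

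Limma called 765 probe sets at 6-9 weeks, 327 higher and 438 lower in males. The count was 369 without female replicate a and 393 without female replicate b of this age, 456 without the intensity trend and 402 when only these groups were fitted. Camera called 13 of 27 lists, 7 higher and 6 lower, and 5 held with an estimated correlation.

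At 24-28 weeks, after puberty, granule genes of neutrophils and their precursors were higher in males, and genes of lymphocytes and of antigen presentation were lower. Prtn3, which encodes proteinase 3, gave 6736 ± 712 in males against 274 ± 9.02 in females (SD, n = 2), a log2 difference of 4.46 (SE 0.13, adjusted p = 1.37e-09). Elane gave 8091 ± 209 against 563 ± 17.5, and Chil3, a chitinase-like gene of myeloid cells, gave 15598 ± 720 against 459 ± 160. Wfdc21 (5.23), Chil3 (5.03), Ngp (3.88), Elane (3.77), Ifitm6 (3.57), Hp (3.19), Ltf (2.99), the annexin gene Anxa1 (2.69) and Gm9706 (2.65) made up the rest of the 10 smallest p-values, and in all 10 both male arrays lay above both female arrays. Of 19 neutrophil genes 14 were higher and 0 lower (median 2.99, adjusted p = 2.06e-20), and adjusted over the list alone 15 were higher.

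The lymphoid lists went the other way in males at this age. Of 22 T cell genes 16 were lower and 0 higher (median −1.11, adjusted p = 3.49e-12), among them Cd3e (−2.53) and Cd8a (−1.78), and adjusted over the list alone 20 were lower. Of 22 B cell genes 17 were lower and 1 higher (median −0.83, adjusted p = 7.16e-10), among them Cd72 (−1.61) and Blk (−1.29), and adjusted over the list alone 18 were lower and 1 higher. Of 10 MHC class II genes 9 were lower (median −1.29, adjusted p = 1.44e-08), such as H2-Ab1 (−1.57), and all 10 adjusted over the list alone. Of 15 NK and cytotoxic genes 9 were lower (median −0.999, adjusted p = 7.87e-06), such as the chemokine gene Ccl5 (−1.52), and 11 adjusted over the list alone. Of 12 dendritic cell genes 8 were lower (median −0.81, adjusted p = 1.03e-05), such as Cd83 (−1.91), and 10 adjusted over the list alone. Of 13 plasma cell genes 4 were lower (median −0.55, adjusted p = 0.000453), such as Irf4 (−1.76), and 8 adjusted over the list alone. The beta-actin ratio of these male arrays was 2.50 against 1.30 in females, and the Gapdh ratio was 2.34 against 1.73.

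Erythroid and dividing cell genes were higher in males at 24-28 weeks. Of 53 cell cycle genes 33 were higher and 0 lower (median 0.59, adjusted p = 4.41e-20), such as Aurka (1.15) and Birc5 (1.14), and 36 adjusted over the list alone. Of 27 erythroid genes 17 were higher and 0 lower (median 0.78, adjusted p = 2.13e-15), such as the transcription factor gene Nfe2 (1.74) and the Rh glycoprotein gene Rhag (1.53), and adjusted over the list alone 21 were higher and 1 lower. Oxidative phosphorylation genes were higher (19 of 63, the same adjusted over the list alone, median 0.16, adjusted p = 9.15e-05). Of 28 interferon-stimulated genes 12 were higher and 6 lower (median 0.34, adjusted p = 0.00553), with Isg15 at 1.92 and Ifit1 at 1.71, and adjusted over the list alone 13 were higher and 7 lower.

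Of 20 pancreas genes 12 were lower and 2 higher in males at 24-28 weeks (median −0.77, adjusted p = 4.26e-07, and adjusted p = 0.0822 with an estimated correlation), and 16 and 2 adjusted over the list alone. The lipase-related gene Pnliprp1 differed by −1.86. The adipose (0.0199), immunoglobulin (0.0171) and cytokine (0.0447) lists were called lower by their adjusted p, with medians of −0.63, −0.48 and −0.22, and with an estimated correlation they gave adjusted p = 0.0774, 0.0822 and 0.0822. They had 3 of 11, 2 of 7 and 7 of 25 members lower and 0, 0 and 1 higher, and adjusted over the list alone 3, 2 and 8 were lower and 0, 0 and 2 higher. The cytokine list was not called without the filter on dim probe sets (adjusted p = 0.226) or with any of 4 single arrays left out (0.0622 to 0.0793), nor the adipose list without female replicate b of this age (0.0581). Macrophage and monocyte genes were not called (median −0.15, adjusted p = 0.796), with 3 of 24 higher, such as Ccr2 (1.44), and 4 lower, such as C1qa (−0.74), and adjusted over the list alone 4 were higher and 6 lower. Liver genes had a median of −0.14 and a mean of 0.35 (adjusted p = 0.468). Limma called 1492 probe sets, 628 higher and 864 lower in males, and 923 without male replicate a or 941 without female replicate a of this age. Camera called 17 of 27 lists, 6 higher and 11 lower, and 12 held with an estimated correlation.

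**Figure D4:**
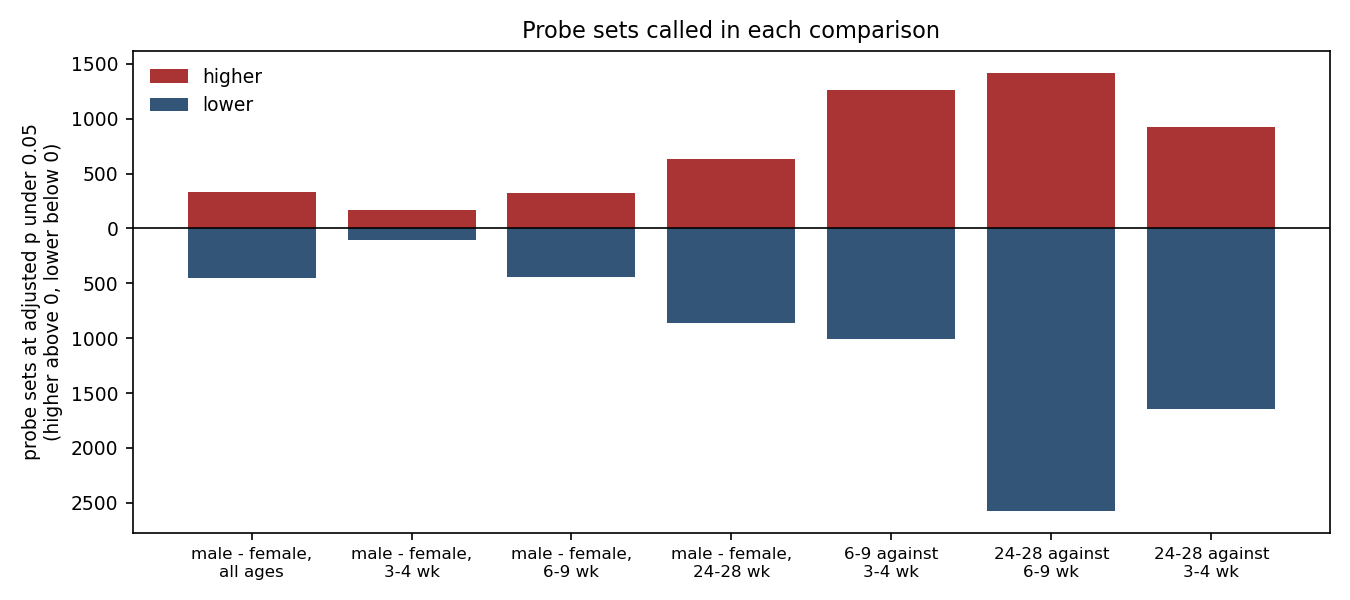
Bars give the number of probe sets at an adjusted p under 0.05 in limma that were higher (red, above 0) or lower (blue, below 0) in each of 7 comparisons. The comparison of 24-28 with 6-9 weeks had 1419 higher and 2573 lower, and the sex difference at 3-4 weeks had 165 and 109.

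The next comparison asked what differed between 6-9 and 3-4 weeks in both sexes. Genes of red cell precursors and of dividing cells fell, and macrophage, T cell and B cell genes rose. The Rh blood group gene Rhd fell from 5465 ± 278 to 1238 ± 11.6 in females and from 5175 ± 35.9 to 766 ± 45.4 in males (SD, n = 2), a log2 difference of −2.41 (SE 0.07, adjusted p = 1.39e-09). All 4 arrays at 6-9 weeks lay below all 4 at 3-4 weeks, as the naming rule required. The other largest separated decreases were Mgst3 (−2.60), Ubac1 (−2.54), Hemgn (−2.39), Tal1 (−2.29), the protease gene Ctse (−2.25), the anion exchanger gene Slc4a1 (−2.22), Urod (−2.20), an enzyme gene of haem synthesis, Rhag (−2.19) and Epb42 (−2.13), a gene of the red cell membrane. Of 27 erythroid genes 24 fell and 1 rose (median −1.47, adjusted p = 1.44e-23), and adjusted over the list alone 25 fell and 1 rose. Of 53 cell cycle genes 44 fell and 0 rose (median −0.70, adjusted p = 1.5e-27), such as Birc5 (−1.82) and Cdk1 (−1.38), and 46 adjusted over the list alone. On all 4 arrays at 6-9 weeks the mean of each of these lists was below that on all 4 at 3-4 weeks. The beta-actin ratio was also lower at 6-9 weeks, at 0.656 and 0.355 in females and males against 1.20 and 1.11.

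The erythroid member that rose was the globin gene Hba-a1, by 4.89 (SE 0.72, adjusted p = 0.000433), but it is uncertain whether its probe set measured that gene, since it ran opposite to the other called members. Its scaled signal differed between the arrays of a group: it was 237.8 and 12.67 in females and 414.6 and 1381 in males at 3-4 weeks, and 15140 and 19430 in females and 8466 and 2319 in males at 6-9 weeks. The other largest separated increases were the immunoglobulin genes Ighv1-54 (2.26), Igkv14-111 (2.24), Igkv6-14 (1.99), Ighv3-6 (1.88) and Igkv9-120 (1.82), and Tbc1d20 (1.73), Kcnab2 (1.66), Galnt11 (1.64) and Rnpep (1.62). Kcnab2 (adjusted p = 0.204) and Galnt11 (adjusted p = 0.102) were not called without the male 6-9 week arrays.

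Of 24 macrophage and monocyte genes 17 rose and 0 fell between 3-4 and 6-9 weeks (median 0.48, adjusted p = 4.32e-07), such as the haem oxygenase gene Hmox1 (0.74) and C1qa (0.66), and 18 rose adjusted over the list alone. Of 22 T cell genes 9 rose and 0 fell (median 0.42, adjusted p = 0.000829), such as Cd8a (0.95) and the interleukin 7 receptor gene Il7r (0.73), and adjusted over the list alone 10 rose and 1 fell. Of 22 B cell genes 8 rose and 1 fell (median 0.29, adjusted p = 0.00176), with Pou2af1 at 0.88 and Cd24a at −1.11, and adjusted over the list alone 10 rose and 1 fell. The MHC class II (6 of 10, adjusted p = 0.0048), cytokine (9 of 25, adjusted p = 0.00176) and complement (7 of 12 up and 1 down, adjusted p = 0.00401) lists rose by medians of 0.47, 0.33 and 0.48, and adjusted over the list alone 7, 12 and 9 of their members rose and 0, 0 and 1 fell. Oxidative phosphorylation genes fell (25 of 63 fell and 3 rose, 27 and 3 adjusted over the list alone, median −0.20, adjusted p = 4.32e-07). Neutrophil genes fell (11 of 19 fell and 2 rose, 12 and 2 adjusted over the list alone, median −0.67, adjusted p = 9.87e-05), such as the eosinophil granule gene Prg2 (−1.95) and Camp (−1.50), but in females alone the median was −0.16 (adjusted p = 0.0873 without the male 6-9 week arrays). The plasma cell (7 of 13 up and 1 down), NK (6 of 15 up) and dendritic cell (5 of 12 up) lists rose by medians of 0.43 (adjusted p = 0.00989), 0.36 (0.0208) and 0.31 (0.0342), and with an estimated correlation they gave adjusted p = 0.0947, 0.0786 and 0.0947. Adjusted over the list alone 7, 7 and 5 of their members rose and 1, 1 and 0 fell. Leaving out male replicate b at 6-9 weeks ended the NK call (adjusted p = 0.0953). The dendritic cell call ended with any of 6 single arrays left out (adjusted p = 0.0516 to 0.0742) and without the filter on dim probe sets (0.0574).

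Limma called 2268 probe sets between 3-4 and 6-9 weeks, 1265 higher and 1003 lower at 6-9 weeks. Without the male 6-9 week arrays, in females only, 1067 were called, of which 943 were among the 2268, and the erythroid (median −1.16, 22 of 27 lower) and cell cycle (median −0.68, 40 of 53 lower) lists were called in the same direction. Camera called 13 of 27 lists, 9 higher and 4 lower, and 10 held with an estimated correlation.

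From 6-9 to 24-28 weeks erythroid and cell cycle genes rose, and genes of T cells, B cells, MHC class II and stroma fell. In females alone the MHC class II list was not called by camera (median −0.03, adjusted p = 0.742). This comparison and the one before share the 6-9 week arrays. The acute phase gene Saa3 rose by 3.63 (SE 0.23, adjusted p = 2.69e-07), to 5287 ± 108 in males and 174 ± 5.92 in females (SD, n = 2). Ighg3, the constant region gene of immunoglobulin G3, rose by 2.66 (SE 0.07, adjusted p = 1.91e-09), from 1038 ± 31.1 to 11434 ± 701 in females and from 1121 ± 43.9 to 4249 ± 73.8 in males. Mgst3 (2.51), Hemgn (2.51), Epb42 (2.32), Gch1 (2.19), Urod (2.18), Tal1 (2.17), the retinal dehydrogenase gene Aldh1a1 (2.15) and the cyclin gene Ccne2 (2.14) made up the other largest separated increases. The largest separated decreases were the transcription factor gene Mef2c (−3.20), Rab11b (−2.56), Ighv14-2 (−2.25), the growth factor gene Tgfb1 (−2.13), Igfbp3 (−2.07), the IgE receptor gene Fcer2a (−2.07), Egln1 (−2.05), Frmd6 (−2.03), Lrp10 (−2.02) and Jund (−2.01). By the naming rule, all 4 arrays of one age lay beyond all 4 of the other for each of these 20 genes.

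Of 27 erythroid genes 23 rose and 0 fell, the same adjusted over the list alone (median 1.06, adjusted p = 2.22e-15), such as Rhd (2.06) and Urod. Of 53 cell cycle genes 35 rose and 1 fell (median 0.45, adjusted p = 3.11e-14), such as Birc5 (1.96) and Mad2l1 (1.71), and 36 and 1 adjusted over the list alone. Oxidative phosphorylation genes rose (38 of 63 rose and 5 fell, 40 and 5 adjusted over the list alone, median 0.43, adjusted p = 2.69e-10), such as Ndufc1 (1.65). The beta-actin ratio was higher at 24-28 weeks, at 1.30 and 2.50 in females and males against 0.656 and 0.355. The Gapdh ratio went from 1.89 to 1.73 in females and from 1.22 to 2.34 in males. Of 22 T cell genes 18 fell and 1 rose (median −0.95, adjusted p = 3.14e-05), such as Cd3e (−1.74) and Cd8a (−1.67), and 19 and 1 adjusted over the list alone. Of 22 B cell genes 18 fell and 1 rose, the same adjusted over the list alone (median −0.82, adjusted p = 2.13e-05), such as Cd37 (−1.76) and Cd79a (−1.54). Of 10 MHC class II genes 9 fell, the same adjusted over the list alone (median −0.79, adjusted p = 0.0015), such as Cd74 (−1.29). Of 35 stroma and matrix genes 22 fell and 1 rose (median −0.72, adjusted p = 7.63e-05), such as the collagen chaperone gene Serpinh1 (−1.25) and the proteoglycan gene Bgn (−1.23), and 23 and 1 adjusted over the list alone. Of 28 interferon-stimulated genes 18 fell and 4 rose, the same adjusted over the list alone (median −0.70, adjusted p = 0.00392), with Irf7 at −1.01 and Isg15 at 1.17.

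Neutrophil genes rose from 6-9 to 24-28 weeks when the sexes were averaged (13 of 19 rose and 1 fell, the same adjusted over the list alone, median 0.77, adjusted p = 3.63e-07), such as Prtn3 (1.94) and Camp (1.65). In females alone, without the male 24-28 week arrays, their median was −0.19 (adjusted p = 0.439) and the MHC class II median was −0.03 (adjusted p = 0.742). The erythroid (0.47, adjusted p = 1.49e-07, 16 of 27 higher), cell cycle (0.13, adjusted p = 0.00219, 11 of 53 higher and 2 lower), T cell (−0.48, adjusted p = 0.022, 7 of 22 lower), B cell (−0.47, adjusted p = 0.0021, 11 of 22 lower) and stroma (−0.50, adjusted p = 0.000338, 15 of 35 lower) medians kept their direction there. So did those of oxidative phosphorylation (0.21, adjusted p = 7.56e-05, 14 of 63 higher and 3 lower) and interferon-stimulated genes (−0.45, adjusted p = 0.0230, 12 of 27 lower and 3 higher). Pancreas genes rose (17 of 20 rose and 1 fell, 18 and 1 adjusted over the list alone, median 0.78, adjusted p = 1.08e-09, and adjusted p = 0.0592 with an estimated correlation), such as Reg3b (1.73) and the lectin gene Zg16 (1.70), and in females alone their median was 2.10 (adjusted p = 2.64e-20, 18 of 20 higher and 1 lower).

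Further calls between 6-9 and 24-28 weeks were lost with an estimated correlation. Macrophage genes fell (15 of 24 fell and 1 rose, 18 and 1 adjusted over the list alone, median −0.55, adjusted p = 0.00417, and adjusted p = 0.0502 with an estimated correlation), such as the growth factor receptor gene Csf1r (−1.61). Endothelial genes fell (9 of 14, and 10 adjusted over the list alone, median −0.64, adjusted p = 0.00921, and adjusted p = 0.057 with an estimated correlation), such as Tie1 (−2.00) and Cdh5 (−1.42). Cytokine (11 of 25 fell and 1 rose, 12 and 1 adjusted over the list alone, median −0.56, adjusted p = 0.0298) and dendritic cell genes (6 of 12 fell, 7 adjusted over the list alone, median −0.39, adjusted p = 0.0454) gave adjusted p = 0.077 and 0.104 with an estimated correlation. In females alone, without the male 24-28 week arrays, these 2 lists gave adjusted p = 0.601 and 0.439, the macrophage median was −0.22 (adjusted p = 0.0298, 7 of 24 lower and 1 higher), the ribosomal protein median was 0.11 (adjusted p = 0.107) and the immunoglobulin median was 0.97 (adjusted p = 7.56e-05, 4 of 7 higher). Neither the cytokine nor the dendritic cell list was called without the filter on dim probe sets (adjusted p = 0.0607 and 0.0611), and any of 6 single arrays left out ended the dendritic cell call (0.0507 to 0.0630). Ribosomal protein genes rose (10 of 28 rose and 3 fell, 12 and 3 adjusted over the list alone, median 0.33, adjusted p = 0.00124, and adjusted p = 0.302 with an estimated correlation). Immunoglobulin genes rose (3 of 7 rose and 1 fell, the same adjusted over the list alone, median 0.44, adjusted p = 0.0212, and adjusted p = 0.0952 with an estimated correlation). The ribosomal (adjusted p = 0.428) and immunoglobulin (adjusted p = 0.0906) lists were not called under quantile normalization.

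Limma called 3992 probe sets between 6-9 and 24-28 weeks, 1419 higher and 2573 lower at 24-28 weeks, or 35.5% higher, and 48.5% of the calls were higher under quantile normalization. The median log2 difference of all probe sets was −0.15, and quantile normalization moved it to 0.014. Without the male 24-28 week arrays 1942 probe sets were called, 1745 of them among the 3992, and without the male 6-9 week arrays 1997 were called, 1778 of them among the 3992. Both are counts of the same comparison in females only. Camera called 16 of 27 lists, 7 higher and 9 lower, and 9 held with an estimated correlation.

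Between 3-4 and 24-28 weeks, the ends of the age range, immunoglobulin and pancreas genes rose when the sexes were averaged, and stroma, B cell, T cell and interferon-stimulated genes fell. In females alone the B cell, T cell and interferon-stimulated lists were not called by camera (adjusted p = 0.349, 0.347 and 0.940). The beta-actin ratio went from 1.20 to 1.30 in females and from 1.11 to 2.50 in males over these ages. The Gapdh ratio went from 2.57 to 1.73 in females and from 2.31 to 2.34 in males. Ighg3 rose by 3.60 (SE 0.07, adjusted p = 3.07e-11), from 509 ± 44.7 in females and 590 ± 44.1 in males at 3-4 weeks (SD, n = 2). The elastin gene Eln fell by 2.16 (SE 0.15, adjusted p = 1.5e-06), from 979 ± 242 to 177 ± 64.3 in females and from 1268 ± 74.7 to 287 ± 18.9 in males. The other largest separated increases were Saa3 (3.96), 1810009J06Rik (2.44), the insulin gene Ins2 (1.99), Igkv8-30 (1.93), Igkv4-91 (1.80), Igkv6-14 (1.75), Igkv14-111 (1.73), Fkbp11 (1.71), a gene of secretory cells, and Ighv1-54 (1.68). Saa3 gave 19.8 to 61.6 on the arrays at 3-4 weeks. At 24-28 weeks it gave 5363 and 5211 in males against 170 and 179 in females. The other largest separated decreases were the transcription factor gene Klf2 (−2.75), Jund (−1.75), Rnf10 (−1.68), Nrep (−1.65), Mef2c (−1.64), Rab11b (−1.64), Ephx1 (−1.64), Pex6 (−1.56) and Tgfb1i1 (−1.52). By the naming rule, all 4 arrays of one age lay beyond all 4 of the other for each of these genes.

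Of 7 immunoglobulin genes 4 rose and 0 fell, the same adjusted over the list alone (median 0.57, adjusted p = 0.000111), with Igha at 1.37 and the joining chain gene Jchain at 1.20. Of 20 pancreas genes 15 rose and 1 fell (median 0.67, adjusted p = 5.4e-13), such as Clps (1.57) and Reg3b (1.46), and 17 and 1 adjusted over the list alone. Of 35 stroma genes 20 fell and 0 rose (median −0.46, adjusted p = 9.9e-05), such as Sparc (−1.21) and Serpinh1 (−1.08), and adjusted over the list alone 22 fell and 1 rose. Of 22 B cell genes 16 fell (median −0.43, adjusted p = 3.54e-05), such as Cd37 (−1.09) and Spib (−1.09), the same adjusted over the list alone. Of 22 T cell genes 13 fell (median −0.51, adjusted p = 0.00037), such as Cd3e (−1.40), and 15 adjusted over the list alone. Of 28 interferon-stimulated genes 19 fell and 2 rose (median −0.50, adjusted p = 4.91e-05), such as Ifit1 (−1.15), and 20 and 2 adjusted over the list alone. Neutrophil genes rose when the sexes were averaged, but not in females alone (9 of 19 rose and 1 fell over both sexes, the same adjusted over the list alone, median 0.39, adjusted p = 4.84e-05), with the protease gene Ctsg at 1.73 and Ngp at −0.67. Oxidative phosphorylation genes rose (27 of 63 rose and 3 fell, 30 and 3 adjusted over the list alone, median 0.21, adjusted p = 2.62e-06).

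In females alone, without the male 24-28 week arrays, several of these list results differed. The neutrophil median was −0.40 (adjusted p = 0.0225, with 5 of 19 lower and 1 higher), the interferon median −0.03 (adjusted p = 0.940), the T cell median −0.09 (adjusted p = 0.347), the B cell median −0.19 (adjusted p = 0.349) and the oxidative phosphorylation median −0.03 (adjusted p = 0.255). The pancreas (1.55, adjusted p = 1.28e-19, 17 of 20 higher), immunoglobulin (0.81, adjusted p = 0.000322, 3 of 7 higher) and stroma (−0.35, adjusted p = 0.0135, 8 of 35 lower and 1 higher) medians kept their direction. Calls on endothelial (4 of 14 fell, median −0.42, adjusted p = 0.0259), plasma cell (5 of 13 rose and 1 fell, median 0.14, adjusted p = 0.0175) and ribosomal protein genes (5 of 28 rose, median 0.14, adjusted p = 0.00441) were lost with an estimated correlation, with adjusted p = 0.104, 0.148 and 0.419, and the members called were as many adjusted over the list alone. The ribosomal list was also not called under quantile normalization (adjusted p = 0.360). In females alone the endothelial list was not called (−0.60, adjusted p = 0.0501, 1 of 14 lower) and the plasma cell median was 0.24 (adjusted p = 0.000523, 4 of 13 higher). Erythroid (median −0.34, adjusted p = 0.0555, 15 of 27 lower and 2 higher) and cell cycle genes (median −0.20, adjusted p = 0.339, 19 of 53 lower and 5 higher) were not called as lists over both sexes. In females alone both were lower at 24-28 weeks, with medians of −0.77 (adjusted p = 1.37e-08, 16 of 27 lower and 1 higher) and −0.61 (adjusted p = 3.04e-10, 32 of 53 lower and 0 higher).

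Limma called 2569 probe sets between 3-4 and 24-28 weeks, 923 higher and 1646 lower at 24-28 weeks, or 35.9% higher, and 47.2% of the calls were higher under quantile normalization. The median log2 difference of all probe sets was −0.13, and −0.015 after quantile normalization. Without the male 24-28 week arrays, in females only, 1350 probe sets were called, 1079 of them among the 2569. Camera called 11 of 27 lists, 6 higher and 5 lower, and 8 held with an estimated correlation.

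The last comparison asked whether the sex difference changed with age. Between 6-9 and 24-28 weeks the male minus female difference of neutrophil and granule genes rose (13 of 19 rose and 1 fell, 13 and 2 adjusted over the list alone, median change 2.001, adjusted p = 1.4e-12). That of pancreas genes fell (17 of 20 fell and 1 rose, 18 and 1 adjusted over the list alone, median −2.14, adjusted p = 1.11e-15). Both held with an estimated correlation (adjusted p = 0.00276 and 0.0215). The beta-actin ratio also changed unequally, from 0.656 to 1.30 in females and from 0.355 to 2.50 in males. The male minus female log2 difference of Prtn3 was 1.35, −0.23 and 4.46 at the rising ages, so it changed by 4.70 (SE 0.18) between the last ages (moderated F test over all ages, adjusted p = 1.37e-07). Igkv8-30 (an _s_at probe set) gave 0.24, 1.39 and −2.83, a change of −4.22 (SE 0.17, adjusted p = 1.38e-07), and its signal at 24-28 weeks was 9095 ± 91.3 in females and 1253 ± 24.3 in males (SD, n = 2). Limma called 1358 probe sets in the F test. Between 3-4 and 6-9 weeks 128 probe sets changed in their sex difference, between 6-9 and 24-28 weeks 1513 did, and between 3-4 and 24-28 weeks 1043 did.

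Of the 27 lists, 4 were not called in any of the 7 comparisons above between sexes or between ages. For the sex difference averaged over ages these were the platelet and megakaryocyte list (median 0.17, adjusted p = 0.243, 0 of 6 called), the sex steroid and glucocorticoid list (median 0.06, adjusted p = 0.285), the skeletal muscle list (median 0.02 against a mean of −0.005, adjusted p = 0.706, 0 of 14 called) and the immediate early and heat shock list (median −0.11, adjusted p = 0.246). Of the 15 sex steroid genes 1 was higher in males, the cortisone reductase gene Hsd11b1 (0.44, adjusted p = 0.001), and the same 1 adjusted over the list alone. Of the 27 immediate early and heat shock genes 2 were higher and 7 lower in males, and 3 and 10 adjusted over the list alone.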

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

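The tests of technical explanations and the fits without the male 24-28 week arrays were chosen after the results were seen, and the tests of a difference between sexes or ages were planned.

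The sex difference changed with age for 1358 probe sets in limma's F test. Of the 791 probe sets called for sex averaged over ages, 379 were among them. Of the probe sets called between ages, 869 of the 2268 for 6-9 against 3-4 weeks, 1048 of the 3992 for 24-28 against 6-9 weeks and 791 of the 2569 for 24-28 against 3-4 weeks were also among the 1358. The F test covers all 3 ages and does not say which age difference differed between the sexes: for 6-9 against 3-4 weeks itself 128 probe sets did. Of 89 named genes of the other comparisons, 55 passed the F test. The 10 genes with the smallest p included neutrophil and secreted defence genes whose male minus female log2 difference rose from 6-9 to 24-28 weeks, namely Prtn3 (4.696), Ngp (4.497), Wfdc21 (4.388), Elane (3.814), Ltf (3.64) and Ifitm6 (2.668). It fell for the immunoglobulin kappa genes Igkv8-30 (−4.215) and Igkv8-19 (−3.186) and for the pancreatic genes Sycn (−3.664) and Pnliprp1 (−3.296). Groups of 2 arrays are too small for a test of single outlying arrays.

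Gene lists were tested for the same change of the sex difference and passed with the preset and with an estimated correlation. From 3-4 to 6-9 weeks the median male minus female difference changed by −0.9643 for neutrophil genes and by −0.3543 for interferon-stimulated genes. From 6-9 to 24-28 weeks it rose for neutrophil (2.001), erythroid (1.354), cell cycle (0.798) and oxidative phosphorylation genes (0.3668). Over the same ages the beta-actin ratio, a sign of RNA quality, went from 0.656 to 1.30 in females and from 0.355 to 2.50 in males. The sex difference fell for pancreas (−2.14), immunoglobulin (−1.244), MHC class II (−1.216), dendritic cell (−1.065), NK (−0.968), T cell (−0.8556), B cell (−0.6828), cytokine (−0.6763) and plasma cell genes (−0.5402). From 3-4 to 24-28 weeks it rose for neutrophil (1.907), erythroid (1.086), cell cycle (0.7819) and oxidative phosphorylation genes (0.3696), and fell for MHC class II (−1.37), pancreas (−1.163), T cell (−1.141), NK (−1.089), interferon-stimulated (−0.8953), dendritic cell (−0.8782), B cell (−0.7551) and cytokine genes (−0.75).

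In males at 24-28 weeks neutrophil genes were higher and T cell, B cell and MHC class II genes lower than in females of that age. A lower share of lymphocytes alone would raise the genes of all other cell types alike, and the tables argue against it: the lower quartile of the neutrophil differences was 1.248 and the upper quartile of the macrophage differences 0.109. Array scaling as the whole cause is argued against by the neutrophil median of 2.829 and the T cell median of −0.97 after quantile normalization (adjusted p = 2.69e-13 for the T cell list). RNA quality cannot be told apart from the group, because the mean beta-actin ratio of these arrays was 2.503 and the highest of the other 10 arrays was 1.37. The Gapdh ratio did not set these arrays apart, at 2.34 ± 0.0511 (SD, n = 2) against 2.31 in males and 2.57 in females at 3-4 weeks. A difference in cell makeup that comes with sex and age may also account for the pattern, and was not tested.

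Pancreas genes rose in females from 6-9 to 24-28 weeks, 18 of 20 being higher and 1 lower. This count is the pattern itself and does not test a varying amount of pancreatic tissue in the samples, which stays open, and the differences were unequal, such as Ppy at 0.14, Ctrb1 at 1.19, Ins2 at 2.98 and Cela2a at −4.51. In males 3 members were higher in limma, namely Reg3b (1.02, adjusted p = 1.61e-05), Zg16 (0.86, adjusted p = 0.000126) and Ins2 (0.67, adjusted p = 0.0485). The 8 lower ones included Rnase1 (−1.62), Cel (−1.36) and Sycn (−1.21). Members thus went both ways, which a varying amount of otherwise like pancreatic tissue alone would not give. This cannot decide the question, because Ins2 passed narrowly and the probe sets of Reg3b and Ins2 can match related transcripts. The makeup of any such tissue was not tested either. None of the 20 genes is in another list, and expression of such genes by spleen cells of either sex or age was not tested and stays open.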

How the results depend on the processing

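The fits without the male 24-28 week arrays and without the male 6-9 week arrays were added after the data were seen, and the other settings were chosen before. The sex difference averaged over ages called 791 probe sets and between 530 and 829 under the settings chosen before, single arrays left out included. Without the eBayes trend the sex difference called 118 probe sets at 3-4 weeks against 274 (111 shared) and 456 at 6-9 weeks against 765 (423 shared), and fits to only the groups compared gave 131 and 402. Fewer arrays, by construction, entered the fits without the male 24-28 week arrays, which called 1942 for 24-28 against 6-9 weeks and 1350 for 24-28 against 3-4 weeks, and those without the male 6-9 week arrays, which called 1067 for 6-9 against 3-4 weeks and 1997 for 24-28 against 6-9 weeks. Over the arrays left out singly, the counts ranged from 106 to 337 for sex at 3-4 weeks, 369 to 738 at 6-9 weeks, 923 to 1523 at 24-28 weeks, and from 963 to 1420 for the F test, where the lone array of a group is assumed to vary like the other groups. The lists called numbered 95 over the comparisons and 58 with an estimated correlation. Quantile normalization lost 8 of the 95 list calls and kept the direction and call of all 122 named-gene results.

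The camera direction turned for several lists without the male 24-28 week arrays. That direction is relative to the other genes, so a median can keep its sign. For the averaged sex difference the medians were −0.2266 (erythroid, adjusted p = 0.00298), 0.02938 (MHC class II, 0.710), −0.03219 (NK, 0.325) and 0.008041 (plasma cell, 0.664). For 24-28 against 6-9 weeks they were −0.008167 (dendritic cell, 0.439) and −0.1864 (neutrophil, 0.439), and for 24-28 against 3-4 weeks −0.02897 (interferon, 0.940), −0.4022 (neutrophil, 0.0225) and −0.0903 (T cell, 0.347). Without the male 6-9 week arrays they were −0.1125 (pancreas, averaged sex difference, 0.0367), −0.07067 (dendritic cell, 0.761) and −0.1864 (neutrophil, 0.384), the last 2 for 24-28 against 6-9 weeks. Only the erythroid list, the neutrophil list against 3-4 weeks and the pancreas list passed in the turned direction. For the age comparisons these fits used females only, so the turned lists show the female difference. The neutrophil value of −0.1864 is thus the same female difference in both fits. Why the sexes or ages differed was not tested. With the letters a and b as a replicate block, 779 probe sets were called for the averaged sex difference against 791, and 93 lists against 95 (complement and stroma for sex at 3-4 weeks, both at an adjusted p of 0.051, were lost). Differences between a and b correlated by −0.066 to 0.059 over 15 pairs of groups, so no shift shared by the arrays of a letter was seen. This does not show how the arrays were handled or where their RNA came from. Detection calls were not used here. With no filter on dim probe sets and with a filter at 200, 710 and 829 probe sets were called for the averaged sex difference against 791, and 3926 and 3778 for 24-28 against 6-9 weeks against 3992. All 8 counts stayed within 1.5 times under both.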

Other observations

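The tests of array scaling and RNA quality, the comparisons within a sex, the values of Hba-a1 and Cela2a and what the splits of the arrays would show were all chosen or written down after the results were seen.

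Within each sex, erythroid genes of red cell precursors fell from 3-4 to 6-9 weeks and rose from 6-9 to 24-28 weeks. In females the median of the 27 genes changed by −1.16 (22 lower, adjusted p = 5.9e-25) and then by 0.47 (16 higher, adjusted p = 5.57e-08). In males it changed by −1.73 (23 lower, adjusted p = 1.3e-23) and then by 1.54 (25 higher, adjusted p = 2.54e-17). Stroma and matrix genes fell in both sexes from 6-9 to 24-28 weeks, with medians of −0.50 in females (15 of 35 lower, adjusted p = 0.000308) and −0.66 in males (21 lower and 1 higher, adjusted p = 0.000912). Neutrophil genes had a median of 2.12 in males (14 of 19 higher and 1 lower, adjusted p = 3.82e-10) and of −0.19 in females (adjusted p = 0.400) over the same ages.

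Within females, limma called 1015 probe sets between 3-4 and 6-9 weeks and 1981 between 6-9 and 24-28 weeks, and within males 1716 and 3923. The globin gene Hba-a1 had signals of 15220 and 10790 in females and 5702 and 582.4 in males at 24-28 weeks, while 17 of 27 erythroid genes were called higher and 0 lower in males. The elastase gene Cela2a fell by 4.51 in females from 6-9 to 24-28 weeks (adjusted p = 0.000456) while 18 other pancreas genes rose. It is uncertain whether either probe set measured the gene it is named for.

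Erythroid and cell cycle genes were lower at 6-9 than at 3-4 weeks in both sexes, and a difference that comes with age was not tested separately and stays open. Array scaling as the whole cause is argued against by medians of −1.355 for erythroid (adjusted p = 7.93e-22) and −0.74 for cell cycle genes (adjusted p = 2.84e-26) after quantile normalization. RNA quality may account for part of it and cannot be told apart from age: over the 6 group means, which are not single arrays, the erythroid mean and the beta-actin ratio had r = 0.8071 (exact permutation p = 0.0472, adjusted over 4 relations 0.0472) and Spearman's rho = 0.829 (exact permutation p = 0.0583, adjusted 0.0583), with r = 0.733 without the 2 groups farthest from the median. With the Gapdh ratio r was 0.906 (exact permutation p = 0.0125, adjusted 0.025) and rho 0.886 (exact permutation p = 0.0333, adjusted 0.0583), with r = 0.799 without 2 groups, and in females that ratio went from 1.89 to 1.73 between 6-9 and 24-28 weeks while erythroid genes rose. For the cell cycle mean these were r = 0.791 (exact permutation p = 0.0417, adjusted 0.0472; 0.587 without 2 groups) and rho 0.829 (0.0583, adjusted 0.0583) with beta-actin, and r = 0.940 (0.00972, adjusted 0.025; 0.873 without 2 groups) and rho 0.886 (0.0333, adjusted 0.0583) with Gapdh. In females the beta-actin ratio was not lower at 24-28 than at 3-4 weeks (1.30 ± 0.0926 against 1.20 ± 0.241, SD, n = 2). Yet in females alone 16 of 27 erythroid genes were lower at 24-28 weeks and 1 higher, and 32 of 53 cell cycle genes were lower and 0 higher. The Gapdh ratio did fall in females over these ages, from 2.57 to 1.73. The beta-actin ratio was low in males at 6-9 weeks with a dim 3' signal, and high in males at 24-28 weeks with a dim 5' signal. Whether it measured RNA quality alike over the groups is therefore uncertain.

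Other splits of the same arrays were tried in an additive model, whose counts are not those of the fit with 6 group means. Sex called 159 probe sets and the highest of the other splits 25, over 100 splits drawn of 462. For 6-9 against 3-4 weeks the counts were 1934 and 32, for 24-28 against 6-9 weeks 2927 and 53, and for 24-28 against 3-4 weeks 1358 and 40, over 35 splits each. In each of the 4 comparisons only 1 split, the real one, gave as many. Splits that divide a group leave the real differences in the residual spread, which holds their counts low, and the labels do not say that the 2 arrays of a group are independent. With the groups kept whole there are only 10 splits for sex and 3 for each pair of ages, too few for a share under 0.05, so whether chance can be excluded stays open.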
